A study of Mus musculus with 3 samples.

How the data were processed

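RNA was measured in MC3T3-E1 cells, a mouse preosteoblast line derived from calvaria, the flat bone of the skull. Per the labels, total RNA was extracted on day 3 of culture, samples with an RNA integrity number over 9.5 were accepted, and biotin-labelled cRNA was made with a 3' IVT kit that copies RNA from its poly(A) tail. It was hybridised to Affymetrix GeneChip mouse genome arrays, on which each gene is read by 1 or more probe sets near its 3' end. There were 3 arrays, 1 for each culture condition. The conditions were taken from the sample descriptions.

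The deposited values of the 45101 probe sets are on a log2 scale, as read from their range of 0.652 to 13.4, since the same numbers taken as powers of e or 10 would exceed a scanner's range. The base itself and the summarisation and normalization that the authors applied are not given in the sources used here. The 3 arrays had medians of 3.54, 3.57 and 3.54 in normal medium, osteogenic medium and osteogenic medium with DMSO, and upper quartiles of 6.27, 6.25 and 6.23, so the arrays had been brought to one scale before deposit. A change in the total RNA of a cell would therefore not be seen. The values are also coarse. Among the 45037 probe sets that are not array controls, the arrays held 14720, 12667 and 13079 distinct values, 37.4% of probe sets had exactly equal values on all 3 arrays, and 68.9% had equal values on at least 2. Equal values give a change of exactly 0 and draw the medians of gene lists towards 0.

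Probe sets were assigned to genes with the platform annotation of 2016, though the symbols supplied include newer names such as Ccn2. Of the 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were not named here. Only probe sets with 1 symbol were used. Of these, 34741 were found by gene number in the GRCm38.p6 gene table, and all 34741 symbols were equal to those of the table. If the symbols had been updated from such a table, this equality is no separate check of the annotation. No coordinates were used. Each of the 18193 genes was represented by its probe set with the highest mean log2 value over the 3 arrays, and 9010 genes had more than 1 probe set. A floor was set at the 50th percentile of all probe sets pooled over the arrays, 3.54, and lower values were raised to it. Of the genes, 11462 were above the floor on at least 1 array and 11203 on all 3. Where 1 of the compared arrays was under the floor, the change is a bound and is written as "at least".

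The comparisons were osteogenic minus normal medium, osteogenic medium with DMSO minus osteogenic medium without it, and, as a secondary comparison, osteogenic medium with DMSO minus normal medium, which is the sum of the other 2. With 1 array per group there is no test and no p-value. A gene was counted as risen or fallen when its log2 difference was at least 1 in size, a 2-fold change. In all, 35 gene lists covering cell type markers, pathways and stress responses were scored by the median log2 change of their members above the floor. Each median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list is described as above or below them when it lay outside their central 95%. That describes these 3 arrays and is not a test of the conditions. Lists with under 5 such members are given as values only. The lists share some members. The single repeat measurement was the agreement between different probe sets of a gene, which covers probe noise and transcript isoforms and leaves out the spread between cultures.

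The genes named are a fixed set of osteoblast genes, the 8 largest rises and 8 largest falls of each main comparison among genes above the floor on both arrays, the 3 largest bounds in each direction, up to 4 members of each described list with the largest changes, and up to 4 genes per pair of directions that changed at least 2-fold in both main comparisons. Names that are only clone numbers were left out. Of the fixed set, Sp7, Alpl, Ibsp, Col1a1, Dmp1 and Phex are reported. Genes without a probe set of a single symbol were not analysed here. Some other list members are named beside them, chosen after their values were seen.

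Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess. The procedure was tested on simulated data for the comparison of osteogenic with normal medium over 18193 genes. All 100 genes raised by 1.5 on the log2 scale and all 50 genes changed by -1.5 were counted as 2-fold changes. None of 50 genes raised by 0.5 was, and 0 of 17993 unchanged genes were. A list of 20 genes raised by 0.5 came out at percentile 100, and 2 of 100 random lists lay outside the central 95%. The changed genes were all well above the floor, the noise had an SD of 0.093 per array, and equal values between arrays were not simulated. Recovery was thus close to fixed in advance. It checks the computation and does not carry over to dim genes, bounds or the coarse deposited values.

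Alternatives were median centring, quantile normalization and cyclic loess of the arrays, floors at the 40th and 60th percentile, an offset in place of a floor, the mean of all probe sets of a gene, leaving out probe sets with the suffixes _x_at and _s_at, a threshold of 1.5-fold, unmatched random lists, and lists without members that another list also holds. These choices, the lists and the rule for named genes were made before the data were examined. One further alternative, gene lists without genes of equal values, was added after seeing the data.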

Results

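Gene expression was measured in MC3T3-E1 mouse preosteoblasts after 3 days at 37 °C in 1 of 3 media. Normal medium was MEM α with 10% fetal bovine serum. Osteogenic medium also held 150 µM ascorbic acid 2-phosphate, a stable form of vitamin C that collagen-making cells need, and 10 mM beta-glycerophosphate, a phosphate donor for mineral. The last condition was osteogenic medium with 0.6% dimethyl sulfoxide (DMSO), a common solvent. Per the labels, alizarin red S staining, which marks calcium deposits, was stronger with 0.6% DMSO. There was 1 array per condition and no replicate, so the spread between cultures is unknown and the number of arrays limits the precision of every value. Changes are log2 differences between 2 arrays. The 3 arrays had 22424, 22539 and 22437 probe sets above the floor, in the order normal medium, osteogenic medium and osteogenic medium with DMSO. Across probe sets, the arrays correlated at Pearson r of 0.997 for osteogenic against normal medium and 0.998 for osteogenic medium with against without DMSO. The 3' minus 5' signal of Actb, a measure of RNA integrity, was 0.27, 0.20 and 0.18. The 18 probe sets of the hybridisation spikes were higher by a median of 0.10 (range 0 to 0.29) on the array of osteogenic than of normal medium, and differed by a median of -0.03 with DMSO.

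The first comparison asked what osteogenic medium changed in 3 days. Several genes of the mature osteoblast rose. Ibsp, which encodes bone sialoprotein, rose 4.52-fold to 10.17 on the log2 scale. Alpl, the alkaline phosphatase that releases phosphate for mineral, rose 3.25-fold from 6.61 to 8.31, and Ifitm5, a membrane protein of osteoblasts, rose 4.12-fold. Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that restrains osteoclast formation, rose 6.96-fold from 5.82 to 8.62. In the other direction, 4 genes of the ATF4 and amino acid response fell, with Trib3 2.67-fold lower and Atf5 2.65-fold lower.

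In all, 54 genes rose at least 2-fold and 21 fell, out of 18193. Of the rises, 9 were bounds. Besides Tnfrsf11b, Ibsp and Ifitm5, the largest rises measured on both arrays were Apcdd1 (2.17 on the log2 scale), an inhibitor of Wnt signalling whose other 4 probe sets ranged from 0.04 to 2.17, Klhl30 (2.01), Lepr (2.00), the leptin receptor, Prss35 (1.90) and Panx3 (1.81), a channel protein of osteoblasts and chondrocytes. Car3, a carbonic anhydrase, went from below the floor to 7.34, at least 13.9-fold higher, while its other probe set differed by 1.03. Inhbb, a subunit of activin and inhibin, was at least 3.09-fold higher, and Bmper, which binds bone morphogenetic proteins (BMPs), at least 2.73-fold higher. The largest falls were Cmbl (-1.53), Vit (-1.51), an extracellular matrix protein, Cdsn (2.82-fold lower), an adhesion protein known from skin, Apobr (-1.44), Trib3 (-1.42), Atf5 (-1.40), the collagenase Mmp13 (-1.40) and the growth factor Fgf18 (-1.33). Abi3bp, Fmo1 and Gprin3 were lower by bounds under 2-fold, at -0.98, -0.94 and -0.90.

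Of the 34 gene lists that could be scored, 12 lay above the central 95% of their random lists and 8 below. Lists of genes drawn independently would put 1.7 outside. Genes of a fixed list can change together and the lists share members, so the excess over 1.7 does not measure an effect of the medium. The osteoblast matrix and mineralization list had a median change of 0.42. Of its 18 measured members, 7 rose, 1 fell and 10 changed less than 2-fold. Smpd3, a sphingomyelinase needed for mineralization, rose by 1.73, Pth1r, the parathyroid hormone receptor, by 1.17, and Dmp1, an acidic matrix protein of late osteoblasts and osteocytes, by 1.17. Phex, a peptidase of osteoblasts and osteocytes, was at least 2.23-fold higher. The abundant collagen genes Col1a1 and Col1a2 differed by 0.04 and 0.03. The transcription factor list had a median of 0.11. Its member Dlx3 rose by 1.41, and Sp7, the factor also called osterix, was higher by 0.88. The osteocyte list, with 7 measured members, had a median of 0.21. It rested on Dmp1, Phex and Capg (0.59), and without members that other lists also hold its median was -0.083.

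The list of BMP and TGF-beta response genes had a median of 0.28, with 1 of 19 members risen, the decoy receptor Bambi (1.13). Inhba and Tgfbi were higher by 0.94 and 0.86, and Id4 was at -0.71. Wnt signalling as a list lay inside its random lists (median 0.00), with Notum, a secreted Wnt inhibitor, risen by 1.66 and Ccn5 at -0.82. Without genes of equal values its median was -0.14, below its random lists. The list of osteoclast-regulating factors had a median of 0.13 over 9 members, led by Tnfrsf11b. In the list of the insulin-like growth factor (IGF) and other growth factors, the median was -0.17. Fgf18 fell and Pdgfa rose by 1.32, while Igf1 and Igfbp5 were at -0.76 and -0.77, with the other probe set of Igfbp5 at -0.14.

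All 25 measured members of the DNA replication list were higher in osteogenic medium, with a median of 0.34, and all 27 of the mitosis list, with a median of 0.37. None of them reached 2-fold. The mitotic kinase Aurka was higher by 0.76, Bub1 by 0.65 and the replication licensing factor Cdc6 by 0.59. The list of p53 targets and cell cycle inhibitors was higher too, with a median of 0.40 and 10 of 14 members above 0. It included Mdm2 (0.84), Cdkn1a (0.82), which encodes the inhibitor p21, and Btg2 (0.78), while Gadd45a was at -0.71. The immediate early list had a median of 0.14, with Dusp6 and Klf2 both at 0.66. Cholesterol synthesis genes had a median of 0.28 and 18 of 20 members above 0. Cyp51 was at 0.70 and Idi1 at 0.55. The lists of fatty acid synthesis and of DNA methylation and demethylation were higher by small medians of 0.07 and 0.09. These, the transcription factor median of 0.11, the osteoclast-regulating median of 0.13 and the immediate early median of 0.14 were of the size of the spikes' difference of 0.10.

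The list furthest below its random lists was the ATF4 and amino acid response, with a median of -0.53. Of its 21 members, 4 fell at least 2-fold and 20 were below 0. Besides Trib3 and Atf5 these were Ddit3 (-1.22), the stress factor also called CHOP, and Aldh1l2 (-1.06), a mitochondrial folate enzyme. Asns, the asparagine synthetase, was at -0.80. The interferon response list had a median of -0.23, with no member changed 2-fold and Gbp2 at -0.79 and the immunoproteasome subunit Psmb9 at -0.63. The list of matrix proteases and inhibitors had a median of -0.12, where Mmp13 and the aggrecanase Adamts5 (-1.02) fell and the inhibitor Timp1 was at 0.46. Smaller medians were those of YAP and SRF targets (-0.12), NRF2 and glutathione genes (-0.10) and ER chaperones (-0.06). Macrophage and osteoclast markers, of which only 6 were measured, had a median of -0.12. The other lists lay inside. Their medians were 0.04 for chondrocyte, cytosolic heat shock, inflammatory and adipocyte genes, 0.03 for oxidative phosphorylation, 0.00 for housekeeping, ribosomal protein, metallothionein, skeletal muscle and glycolysis genes, -0.02 for smooth muscle, -0.04 for fibrillar matrix and -0.06 for collagen processing. The chondrocyte list nonetheless held a rise of Col11a2 (1.38), and the metal handling list one of the iron exporter Slc40a1 (at least 2.14-fold). Endothelial markers had 4 measured members and a median of -0.06.

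Pairs of probe sets were compared for 5183 of the 9010 genes with more than 1 probe set. The log2 changes of a pair scattered with an SD of 0.13. Among these 5183 genes, 25 of 28 changed 2-fold had the same sign in the second probe set. Another probe set showed a smaller change for Lepr (0.43), Panx3 (0.98), Inhbb (0.23), Dlx3 (0.10), Slc40a1 (0.29), Angpt4 (0.33), Bub1 (0.20), Cyp51 (0.38), Ddit3 (-0.63) and Adamts5 (-0.48). The calls of Lepr, Panx3, Prss35, Inhbb, Bmper, Dlx3, Phex, Bambi, Col11a2, Slc40a1, Angpt4, Il33, Ddit3 and Adamts5 were lost under at least 1 alternative, as were the positions of the transcription factor, osteocyte, osteoclast-regulating, fatty acid, ER chaperone and macrophage lists. Under at least 1 alternative, the chondrocyte and inflammatory lists moved above their random lists and the fibrillar matrix, collagen processing, Wnt and smooth muscle lists below.

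**Figure D1:**
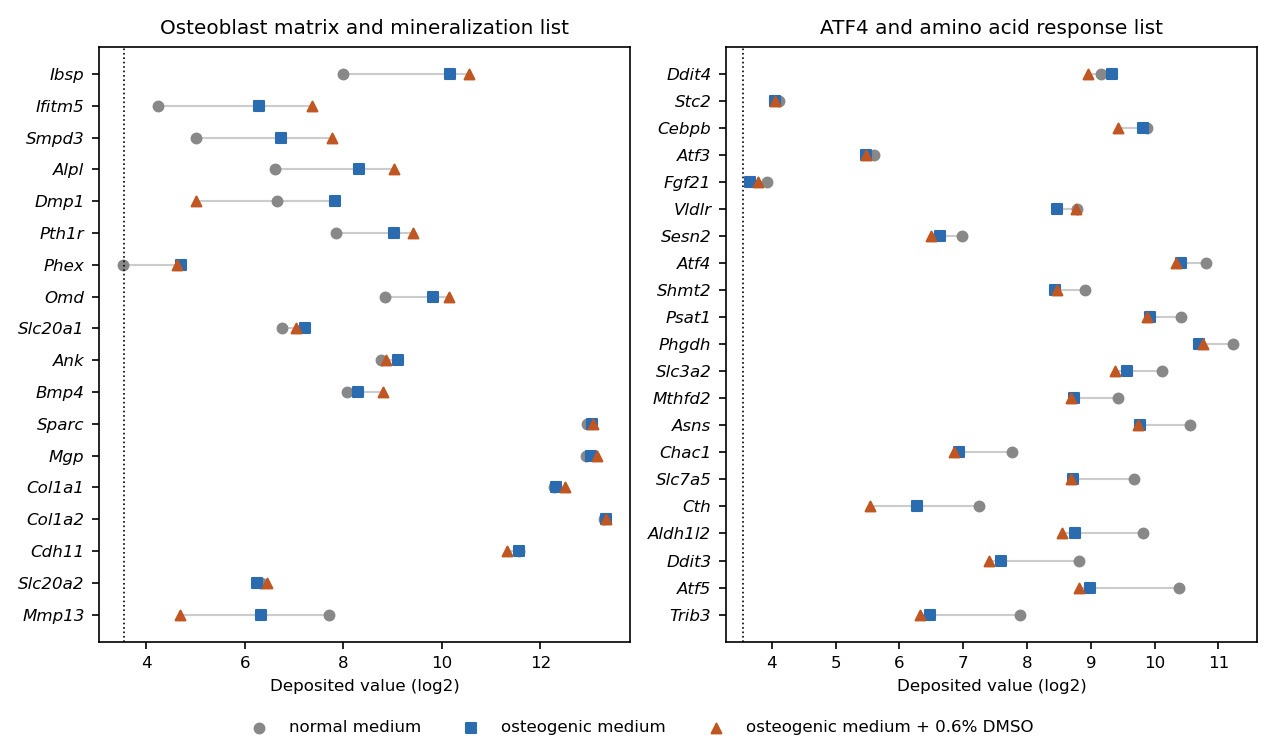
Deposited log2 values of the members of the osteoblast matrix and mineralization list (left) and the ATF4 and amino acid response list (right) on the 3 arrays, with the floor of 3.54 as a dotted line. Ibsp, Ifitm5, Smpd3 and Alpl step up from normal to osteogenic medium and again with DMSO, Dmp1 goes up and then down, and 20 of 21 members on the right are lower in osteogenic than in normal medium.

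The second comparison asked what DMSO changed within osteogenic medium by day 3, where the labels report stronger alizarin red S staining. Many more genes fell than rose. F13a1, the catalytic subunit of a transglutaminase that crosslinks matrix and fibrin, fell 12.2-fold from 9.11 to 5.51. Sostdc1, a secreted antagonist of BMP and Wnt signals, was 7.41-fold lower and Dmp1 7.03-fold lower. Crabp1, which binds retinoic acid in the cell, was 6.74-fold lower, and Aldh1a3, an enzyme that makes retinoic acid, fell by 2.38 on the log2 scale from 9.01 to 6.63. Among the few genes that rose were Car3 (3.34-fold), Ifitm5 (2.12-fold) and Smpd3 (2.04-fold), which had also risen with osteogenic medium.

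In all, 6 genes rose at least 2-fold and 63 fell, with 10 of the falls as bounds. The other rises were Slc8a3 (1.10 on the log2 scale), a sodium-calcium exchanger, the corepressor Tle4 (1.07) and Tmem243 (1.02). Ramp1, a partner of the calcitonin receptor-like receptor, and the transcription factor Mef2c were higher by 0.99 and 0.88. Further falls were Cnmd (-2.12), which encodes chondromodulin, the aminopeptidase Enpep (-1.90) and Otor (-1.87). Cldn1, a tight junction protein, was at least 3.43-fold lower, Krt14, a keratin, at least 2.95-fold and Ntrk3, a neurotrophin receptor, at least 2.81-fold, though a second probe set of Ntrk3 stood at 0.11. Bounds in the upward direction were under 2-fold, at 0.87 for Hpse, 0.80 for Abi3bp and 0.69 for Cd24a. The 3 probe sets of Dmp1 changed by -2.81, -2.63 and -1.76.

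The osteoblast matrix and mineralization list lay above its random lists with a median of 0.15, though its members went both ways. Of 18, 2 rose (Ifitm5 and Smpd3), 2 fell (Dmp1 and Mmp13, at -1.63) and 14 changed less than 2-fold. Alpl was higher by 0.71, Bmp4 by 0.52, Ibsp by 0.38 and Col1a1 by 0.18, and Phex was at -0.07. Sp7 was higher by 0.41. The osteoblast transcription factor list had a median of 0.00 and the osteocyte list one of -0.07, both inside their random lists, though the former lay above with the floor at the 60th percentile (0.077). Replication and mitosis genes were again higher, with medians of 0.18 and 0.21 and 23 of 25 and 26 of 27 members above 0. Among these were Ccne2 (0.49) and Bub1 (0.38). Oxidative phosphorylation genes also lay above, by a median of 0.07 with 20 of 25 members above 0 and the other 5 equal.

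Below their random lists lay 15 of 34 lists. The list of IGF and other growth factors had the lowest median, -0.31. Igf2 fell by 1.45, with its other probe set at -0.31, and Fgf7, Igfbp5 and Igf1 were at -0.73, -0.69 and -0.66, with the other probe set of Igfbp5 at -0.07. Adipocyte genes, with 10 measured members, had a median of -0.30 and none above 0, with Zfp423 at -0.60 and Fabp5 at -0.57. Osteoclast-regulating factors had a median of -0.26, with Ptgs2, which makes prostaglandins, at -0.76 and the vitamin D receptor Vdr at -0.69, while Tnfrsf11b was at 0.08. In the inflammatory list (-0.19), the chemokine Ccl2 was at -0.74 and Nos2 at 0.36, and in the interferon list (-0.21) Bst2 and H2-D1 were both at -0.56.

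The YAP and SRF target list had a median of -0.19, Ankrd1 fell by 1.17 and Ccn2, the connective tissue growth factor, was at -0.78. No member of the smooth muscle list was above 0 (median -0.17), and its kinase Mylk was at -0.84. Fibrillar matrix genes had a median of -0.11, with 19 of 25 below 0 and Col5a3 and the proteoglycan Lum at -0.73 and -0.69. The list of matrix proteases and inhibitors had a median of -0.14, and Mmp13 and the inhibitor Timp3 (-1.20) fell. In the BMP and TGF-beta list (-0.13), Id4 fell by 1.83 and Tgfbi and the BMP antagonist Grem1 were at -0.88 and -0.87, while Bambi was at 0.55 and Id3 at 0.47. The p53 target list had a median of -0.14 with all 14 members below 0, led by Mdm2 (-0.45). The cholesterol list had a median of -0.15, with Msmo1 at -0.32 and Dhcr7 at 0.28. The ATF4 list was at -0.07, where Cth, which makes cysteine, was at -0.73 and Vldlr at 0.30, with other probe sets of Vldlr from -0.067 to 0.35. The immediate early list was at -0.05, with Klf2 at 0.67 and Jun at -0.50, and the 6 macrophage and osteoclast markers at -0.14.

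The remaining lists lay inside. Wnt signalling, NRF2, ER chaperone, housekeeping, ribosomal protein, metallothionein and skeletal muscle genes had medians of 0.00. The Wnt list held a fall of Rspo2 (-1.30), which amplifies Wnt signals, and Wnt4 and Notum were higher by 0.66 and 0.61. In the skeletal muscle list Tnnc1, a troponin, fell by 1.77. Collagen processing had a median of -0.01 with a fall of the prolyl hydroxylase P3h2 (-1.11). The medians were 0.03 for DNA methylation, 0.02 for glycolysis, 0.01 for heat shock, -0.01 for fatty acid synthesis and -0.04 for chondrocyte genes. The 4 measured endothelial genes had a median of 0.00.

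The SD between probe sets of a gene was 0.11 in this comparison, over the same 5183 genes. All 19 genes changed 2-fold among these had the same sign in the second probe set. Ntrk3, whose fall is a bound, is not among the 19, and its other probe set had the opposite sign (0.11). The agreement therefore does not cover every 2-fold change of a gene with a second probe set. Another probe set showed a smaller change for Car3 (1.04), Ramp1 (0.12), Krt14 (-0.72), Rspo2 (-0.04), Angpt4 (-0.33), Wnt4 (0.29), H2-D1 (0.00), Bub1 (0.00), Igf1 (-0.37) and Col1a1 (-0.0068). Each of the 6 rises was lost under at least 1 alternative, as were the falls of Ntrk3, Cldn1, Krt14, Igf2, Rspo2, P3h2, Angpt4 and Il33 and the positions of the oxidative phosphorylation and macrophage lists. Besides the transcription factor list, the Wnt (-0.096 without genes of equal values), chondrocyte, collagen processing and ER chaperone lists moved outside under 1 alternative each, all of them below.

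**Figure D2:**
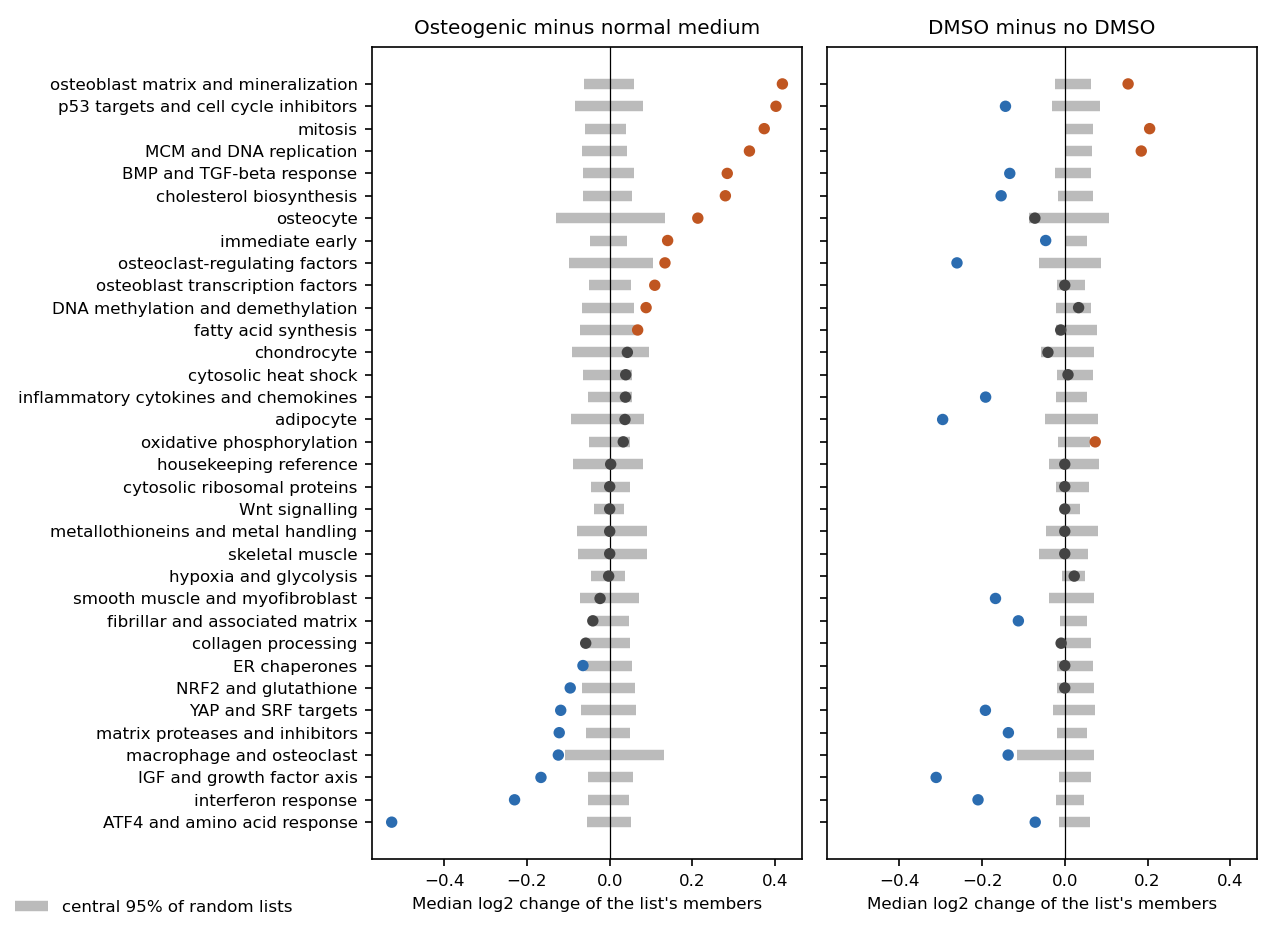
Median log2 change of each of 34 gene lists (points) in osteogenic against normal medium (left) and with against without DMSO (right), with the central 95% of matched random lists as grey bars; orange points lie above and blue points below. Osteoblast matrix, mitosis and replication genes lie above on both sides, and the cholesterol, p53, BMP, osteoclast-regulating and immediate early lists go from above to below. The array of osteogenic medium without DMSO is on both sides with opposite signs, so a deviation of that culture alone would also give the latter pattern.

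The array of osteogenic medium without DMSO is in both comparisons with opposite signs, so its noise alone pushes them apart. Across the 11203 genes above the floor on all arrays, which are not independent replicates, the 2 changes had a Pearson r of 0.064 and a Spearman rho of 0.036. Equal noise on each of the arrays gave a simulated r of -0.504. Noise of any size gives about that value, so its distance from 0.064 tests nothing about these arrays. The covariance was 0.00307 against a simulated -0.00871, a difference of 0.0118. The simulated noise had the SD seen between probe sets in the first comparison, 0.13, and not the 0.11 seen with DMSO. With the 2 changes taken from separate probe sets of 5183 genes, r was 0.113. With both changes from the same probe set of these genes it was 0.116. The difference from 0.064 therefore came with the set of genes and not with the separate probe sets. Among the 11203 genes, Ifitm5 and Smpd3 rose at least 2-fold in both, where independent lists would share 0.0201 genes. Sostdc1, Dmp1 and Angpt4, an angiopoietin, rose and then fell (0.213 for independent lists), Mmp13 fell in both (0.0946), and 0 genes fell and then rose. Car3 rose in both and the cytokine Il33 rose and then fell, with bounds where they were below the floor. Both calls of Angpt4 and both of Il33 were lost under at least 1 alternative. Of the 45 genes that rose 2-fold with osteogenic medium, 20 were higher again with DMSO and 25 lower, with a median of -0.09, a tally that noise of the shared array pulls down. With the rise taken from 1 probe set and the DMSO change from another probe set of the same gene, 19 of 37 rises, from 25 genes, had a DMSO change above 0 and 15 below, with a median of 0.02.

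**Figure D3:**
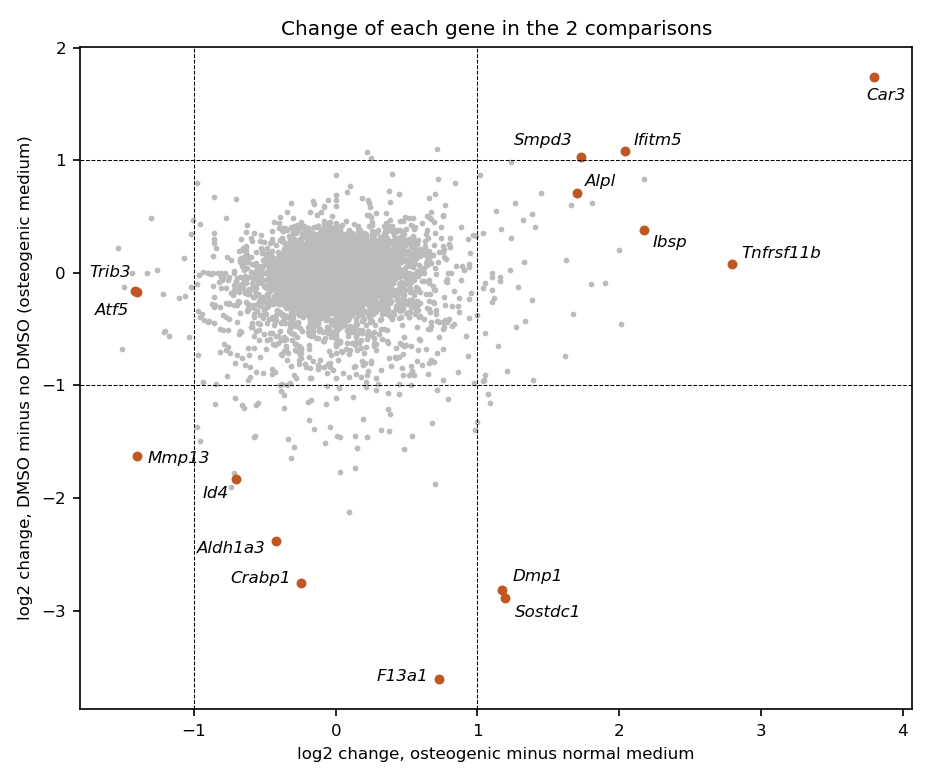
Log2 change of 11462 genes in osteogenic against normal medium (horizontal) and with against without DMSO (vertical), with dashed lines at 2-fold. Car3, Ifitm5 and Smpd3 lie above both upper lines, Dmp1 and Sostdc1 at the lower right, and Crabp1, Aldh1a3 and F13a1 change mainly with DMSO.

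Against normal medium, the cells in osteogenic medium with DMSO had 69 genes risen and 153 fallen at least 2-fold. Alpl was 5.33-fold higher, Ibsp 5.89-fold, Sp7 2.45-fold and Phex at least 2.12-fold, while Dmp1 was 3.12-fold lower. Of the 34 lists, 8 lay above and 13 below their random lists. Medians were 0.25 for osteoblast matrix, 0.56 for replication and 0.60 for mitosis genes, and -0.56 for growth factors, -0.53 for the ATF4 response and -0.48 for interferon genes. Of the lists that went from above to below, the BMP (0.00), osteoclast-regulating (-0.08) and immediate early (0.03) lists lay inside here. The p53 target (0.19) and cholesterol (0.16) lists lay above. A deviation of the single culture without DMSO cannot be told apart from an effect of DMSO on these lists. When probe sets with the suffixes _x_at and _s_at were left out, Dmp1 was under 2-fold lower, at -0.59, and the bound of Phex was 0.15 with the floor at the 60th percentile.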

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

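No paired analysis was possible because each condition had 1 array, and for the same reason no array could be left out. Of 39 lists outside their random lists in the 2 main comparisons, 31 stayed there under all 11 alternatives run, 7 moved inside under at least 1, and 1 reversed: the osteocyte list in osteogenic medium went to -0.083 once the members it shares with other lists, Dmp1 and Phex, were left out. Of 29 lists inside, 11 moved outside under at least 1. Of 67 changes of named genes past 2-fold, 37 kept their call under all 8 alternatives that apply to genes and 0 reversed. With an offset in place of a floor, which by construction shrinks the changes of dim genes, 30 genes rose in osteogenic medium, and with DMSO 1 rose, Car3, and 41 fell. With the mean of all probe sets of a gene, 1 gene rose with DMSO, Ifitm5, since Car3 averaged 0.69. At a threshold of 1.5-fold, 200 genes rose and 184 fell in osteogenic medium, 40 and 242 with DMSO, and 296 and 479 in osteogenic medium with DMSO against normal medium. All other counts of 2-fold changes stayed within 1.5 times the reported ones. Median centring, quantile normalization and cyclic loess moved the median of all genes by at most 0.03. Signal over background limits what can be said of dim genes: the SD between probe sets was 0.15 in the dimmest and 0.11 in the brightest range of mean expression in the first comparison, and bounds of genes such as Inhbb, Bmper and Phex fell under 2-fold with the floor at the 60th percentile.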

Other observations

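The tests of a general further rise with DMSO and of scaling for the replication and mitosis genes were chosen only after the results were seen, and the aminoacyl-tRNA synthetase and retinoid lists were drawn up after single genes had been looked at.

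A pair of gene groups outside the fixed lists also differed. Aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA, were lower in osteogenic than in normal medium, with a median of -0.31 and 14 of 19 below 0. Aars was at -0.80, Sars at -0.59, Nars at -0.56 and Lars at -0.51, while Kars, Rars and Vars had equal values on both arrays. With DMSO, genes of retinoid metabolism and response were lower, with a median of -0.22 and 7 of 10 below 0 in a list that leaves out Aldh1a3, Crabp1 and Tgm2 (-1.55). Adh1, an alcohol dehydrogenase, was at -0.84, the binding protein Crabp2 at -0.69 and Aldh1a1 lower by a bound of -0.65. Cyp26a1 and Cyp26b1, which break down retinoic acid, were at -0.32 and -0.27, the former near the floor. The receptor genes Rara and Rarg were at 0.00 and 0.03. Array controls varied too, besides the hybridisation spikes. The 3' probe set of 18S ribosomal RNA read 11.56, 10.82 and 11.29 in normal medium, osteogenic medium and osteogenic medium with DMSO, and the probe set of the B1 repeat read 11.56, 11.69 and 12.17.

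With DMSO, 63 genes fell and 6 rose at least 2-fold. A trend with brightness left in the deposited values would shift the median change of a brightness range. Of the 3 ranges, the median furthest from 0 was 0.00846. However, 29.6% of the genes above the floor on both arrays had equal values, which draws such medians towards 0. The medians therefore argue only against a large leftover trend. Falls outnumbered rises in each range, by 18 to 4, 23 to 1 and 12 to 0 from dim to bright. The arrays had been scaled before deposit, so what that step did to such a trend cannot be seen. Scaling between the arrays stays open. Under median centring, quantile normalization and cyclic loess the falls outnumbered the rises by 8.71 times or more, but these moved the median of all genes by at most 0.024 and so could hardly have changed the counts. A difference between single cultures that DMSO did not make is also open with 1 array per condition.

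Replication and mitosis genes were higher in osteogenic medium and higher again with DMSO. All 4 list medians lay at percentile 100 of random lists of like expression, which scaling between the arrays would move as well. These percentiles are also what marked the lists as higher, so they are no separate test of scaling. They show only that the lists stood apart from genes of like expression. A difference in growth stage or cell density between the 3 cultures, with 1 culture per condition, cannot be told apart from an effect of the media.

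The ATF4 and amino acid response genes were lower in osteogenic medium. Single misleading probe sets are argued against, because of 17 members at least 1.2-fold lower, 10 had a second probe set and 100% of these were lower in it too. A lower amino acid response may underlie the pattern: it calls for lower aminoacyl-tRNA synthetases, and their list lay at percentile 0 of its random lists. No other explanation was given a prediction for the aminoacyl-tRNA synthetases. The result therefore cannot tell a lower amino acid response from another cause of a lower ATF4 list. A general loss of ER stress signalling stays open, since the ER chaperone list lay at percentile 1.905 but moved inside under 4 of 11 alternatives, with a range of 1.43 to 8.64. The chaperones' median of -0.06 was small beside the -0.53 of the ATF4 list.

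A further hypothesis is that DMSO may lower retinoid signalling in these cells, as the falls of Aldh1a3 and Crabp1 led to asking. The retinoid list lay at percentile 0.02 of its random lists, as a lower retinoid response would give. For osteogenic medium with DMSO against normal medium, it lay inside, at a median of -0.07 and percentile 4.55. In that comparison 7 of 10 members were below 0, with Adh1 at -1.05 and Crabp2 at -0.74. Cyp26a1 and Cyp26b1 were at 0.10 and -0.02 there. A deviation of the single culture without DMSO is therefore not set aside. The lower members of the list include enzymes and the binding protein Crabp2, and a loss of the cells that make them is not set aside by this test. Whether DMSO moves the genes raised by osteogenic medium further in general stays open. With separate probe sets for the rise and the DMSO change, 51.4% of the rises were higher with DMSO, but the culture without DMSO is in both changes and pulls this share down. Within 1 group of osteoblast genes the directions parted, with Ifitm5, Smpd3 and Alpl higher and Dmp1 lower.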
